A study of Homo sapiens with 8 samples.

How the data were processed

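The series measured trimethylation of histone H3 at lysine 9 (H3K9me3) by chromatin immunoprecipitation and sequencing (ChIP-seq) in H9 cells (WA09), an established human embryonic stem cell line. Cells stably expressing a short hairpin RNA (shRNA) against HTT, the gene of huntingtin, were compared with cells expressing a non-targeting (NT) shRNA. Each group held 2 replicates, which the design text describes as biological and as coming from separate experiments. Every immunoprecipitated library had an input library of its own, and the labels name 1 input beside each peak list. Lines were made with lentivirus and selected with puromycin, per the labels' protocols.

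The deposited files were 8 peak lists, 1 broad and 1 narrow list for each of the 4 immunoprecipitated libraries, so peaks were called per library and not on pooled samples. The submitters' processing notes name CASAVA, with no version, and the genome build hg38. The aligner, the peak caller and their settings are not given in the sources used here. The files give each peak's start and end and a fold enrichment, which is a linear ratio computed by the authors, per the file headers. This fold belongs to the peak and was used only to describe, rank or filter peaks within a list. A p-value column is also present per the file headers. It was filled only for peaks that carried a gene identifier, its meaning is not stated, and it was not used. No read counts were analysed here, so the sequencing depth of each library is unknown and no counting error can be given.

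Each of the 8 lists held exactly 65535 data rows, sorted by chromosome name as text, and broke off at that row. A list therefore held only part of the genome, and the last chromosome differed between lists. Chromosomes 1, 2 and 10 to 19 stood complete in all 4 broad lists, and these 12 chromosomes, spanning 1529 Mb, were used for every comparison in place of the planned chromosomes 1 to 22 and X. This choice was made after the row limit had been seen. In the narrow lists 11 chromosomes were complete (1 and 10 to 19). Without NT shRNA replicate 1, the broad list that ended earliest, 19 chromosomes were complete in the broad lists (1 to 6 and 10 to 22). A file holds 1 row for each pair of a peak and a neighbouring gene, and each peak was counted once.

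Gene positions came from the RefSeq annotation of GRCh38, the assembly that hg38 denotes. The gene identifiers in the lists could not be paired with gene symbols, so genes were assigned by coordinates. Protein-coding genes placed on alternate or unplaced sequences (177) were left out, and 11577 protein-coding genes lay on the 12 chromosomes. The table gives no strand, exons or UTRs, so a peak is placed only inside or outside a gene body.

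Broad lists were the main lists. For each library the covered length, the number of peaks, the mean and median width and the number of 10 kb windows with a peak were computed. Group values were compared as the log2 ratio of the group means, with a two-sided exact permutation test over the 6 assignments of the 4 libraries to groups of 2. The smallest p this design can give is 0.333, so no such test can pass 0.05. Shared length was given as the Jaccard index, the base pairs covered by both libraries over those covered by either. Broad peaks of the 4 libraries were merged into regions. A region was HTT-only where both HTT shRNA libraries and neither NT shRNA library had a peak on it (overlap of 1 bp or more), and NT-only in the opposite case. Genes were classed in the same way by peaks over the gene body. These counts were set beside those of the other ways of splitting 4 libraries into 2 pairs, 3 splits in all.

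The 17 gene lists, the rule for named genes, the tests and the first group of alternatives below were fixed before the data were examined. The lists were H3K9 methylation machinery, pluripotency, neural, mesoderm and endoderm lineage, trophoblast and other extraembryonic genes, fibroblast and mesenchymal genes, imprinted genes, germline genes, housekeeping genes, synaptic adhesion and receptor genes, mitochondrial respiratory chain, zinc finger genes, clustered protocadherins, olfactory receptors, canonical histone genes and cancer-testis antigens. The number of members with a peak was ranked among 10000 random lists matched on gene length. HTT-only and NT-only members were compared with all other genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 30 tests of the 15 lists with 5 or more members. Neighbouring genes share H3K9me3 domains and are not independent, so these p-values describe these libraries.

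Genes are named by rule. For each direction these are the 10 protein-coding genes with the largest covered length, taking the smaller value of the marked pair of libraries. HTT, ATF7IP and SETDB1 are named in any state, as are at most 4 HTT-only or NT-only members of each list and, per list, the 2 members marked in all 4 libraries with the largest covered length in the library where it was smallest. The 5 HTT-only and the 5 NT-only regions of largest covered length, again by the smaller value of the marked pair, are given by position.

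The first group of alternative settings comprised the narrow lists, a fold enrichment of at least 4, the same number of peaks (30983) from every list, joining of peaks closer than 1 kb, other overlap rules, random lists matched on length and chromosome, a replicate block, and leaving out each library in turn. Settings chosen after seeing the data were peaks of 300 bp or wider, peaks at or above the median fold of their list, joining within 5 kb, removal of peaks that touch a peak over 50 kb, 10 kb windows, gene bodies with 2 kb on each side, a crossed block, the difference of mean log2 values, and the 19 chromosomes of 3 lists. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The interval code was tested on simulated data, with 0 mismatches in 200 simulated sets of intervals. All of the 200 regions planted in each direction were recovered among 46563 regions, with 0 others called. The real HTT-only and NT-only regions had been removed first and the planted ones held no noise. The result therefore checks the code and gives no error rate for these classes. Of 100 random gene lists, 6 fell below the 5th or above the 95th percentile of their matched lists.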

Results

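H3K9me3, a histone mark of silenced chromatin, was mapped by ChIP-seq in H9 human embryonic stem cells expressing an shRNA against HTT or a non-targeting (NT) shRNA, with 2 replicates per group. The series title names suppression of H3K9 trimethylation in pluripotent cells as its subject, and the design compares the mark between these groups. Broad peaks called by the authors in each library were compared on chromosomes 1, 2 and 10 to 19, the part of the genome held in full by all 4 lists. On these chromosomes the lists held 37380 and 38999 peaks in HTT shRNA replicates 1 and 2, and 61346 and 30983 peaks in NT shRNA replicates 1 and 2. Read depth is unknown. Peak lists measure no RNA, so the knockdown of HTT itself could not be checked on them.

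In all 4 libraries H3K9me3 was most extensive on chromosome 19, which carries many zinc finger gene clusters. Peaks covered 13.3% and 11.0% of that chromosome in HTT shRNA replicates 1 and 2, 4.16% in NT shRNA replicate 1 and 22.1% in NT shRNA replicate 2. The corresponding shares of chromosome 2 were 3.77%, 3.60%, 0.829% and 4.97%. Over the 12 chromosomes the covered length was 65.2 and 63.6 Mb in the HTT shRNA libraries, and 17.2 and 113.3 Mb in the NT shRNA libraries.

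The NT shRNA libraries lay on either side of the HTT shRNA libraries, and the group means of the covered length were close. They were 64.4 ± 1.15 Mb (SD, n = 2) with HTT shRNA and 65.3 ± 68.0 Mb (SD, n = 2) with NT shRNA, a log2 ratio of -0.02 (exact permutation p = 1, two-sided). The ratio was -1.74 with a fold enrichment of at least 4 and -0.62 with the narrow lists. Values per library are not given for these settings, so the part of a single NT shRNA library in them is unknown. The median fold differed between lists (2.24 and 2.05 with HTT shRNA, 1.90 and 2.44 with NT shRNA), so a fixed fold does not cut them alike. Peak number averaged 38190 ± 1145 (SD, n = 2) with HTT shRNA and 46165 ± 21470 (SD, n = 2) with NT shRNA, a log2 ratio of -0.27 (exact permutation p = 1, two-sided). At the main settings both differences were far smaller than the spread between the NT shRNA replicates. The log2 ratio of covered length was -0.82 without NT shRNA replicate 1 and 1.91 without NT shRNA replicate 2. For peak number it was 0.30 and -0.68, so a single NT shRNA library set the direction of both ratios.

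**Figure D1:**
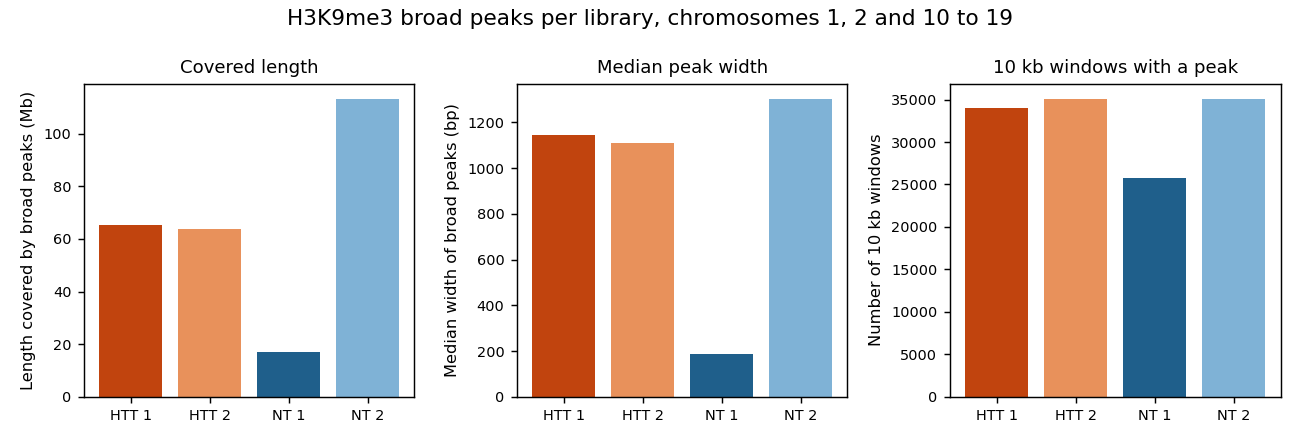
Length covered by H3K9me3 broad peaks in Mb (left), median peak width in bp (middle) and number of 10 kb windows with a peak (right), each bar being 1 library. The HTT shRNA libraries cover 65.2 and 63.6 Mb, between the NT shRNA libraries at 17.2 and 113.3 Mb, while HTT 1, HTT 2 and NT 2 have peaks in 34059, 35033 and 35118 windows and NT 1 in 25752.

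Peak width separated the NT shRNA libraries from each other. The median broad peak was 1144 and 1108 bp wide in the HTT shRNA libraries, 186 bp in NT shRNA replicate 1 and 1304 bp in NT shRNA replicate 2. Peaks wider than 50 kb numbered 8 in each HTT shRNA library, 0 in NT shRNA replicate 1 and 302 in NT shRNA replicate 2, where they made up 36.3% of the covered length. The number of 10 kb windows with a peak differed less, at 34059 and 35033 in the HTT shRNA libraries, 25752 in NT shRNA replicate 1 and 35118 in NT shRNA replicate 2.

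The libraries marked overlapping parts of the genome. HTT shRNA replicate 1 had 78.4% and HTT shRNA replicate 2 had 73.0% of its covered length inside peaks of NT shRNA replicate 2, which covered 7.41% of the span. NT shRNA replicate 1 had 87.2% of its covered length there. The Jaccard index was 42.7% between the HTT shRNA libraries and 13.0% between the NT shRNA libraries. Its mean was 27.8% within groups and 27.5% between groups, a difference of 0.341 percentage points. The other splits of the 4 libraries gave differences of -1.89 and 1.55 points. At the main settings the real grouping thus gave a smaller excess than a pairing across the groups. The index is limited by the sizes of both lists, and the NT shRNA lists (17.2 and 113.3 Mb) differed most in size. For the real grouping the difference was 6.63 points with a fold enrichment of at least 4 and 2.27 in the narrow lists. It was 6.17 for the share of peaks overlapped over at least 50% of their length. The other splits are not given for these settings. The difference ranged from -15.7 points without HTT shRNA replicate 2 to 25.6 points without NT shRNA replicate 2. With 1 library left out, only the NT shRNA pair (13.0%) or the HTT shRNA pair (42.7%) remains within groups. The sign followed which pair remained, so this range does not measure the weight of a single library.

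Zinc finger genes, many of which encode repressors of transposable elements, carried the mark at similar numbers of members in the 4 libraries. Of 396 family members 283 and 289 had a peak in the HTT shRNA libraries and 273 and 279 in the NT shRNA libraries, with 260 marked in all 4. The covered share of their summed length differed more, at 22.9% and 21.98% with HTT shRNA and 9.87% and 27.7% with NT shRNA. The member counts lay above those of the length-matched random lists in each library (percentile 100). ZNF69 (chromosome 19, 11887782 to 11980222) was covered over 59.2% and 58.5% of its body with HTT shRNA and over 37.5% and 62.5% with NT shRNA. For ZNF544 the shares were 65.6%, 69.6%, 48.5% and 73.9% in the same order. Among HTT-only genes 7 were zinc finger genes, at 6 loci more than 1 Mb apart, and among NT-only genes 0 were (Fisher's exact test, adjusted p = 1 in both directions). The named HTT-only members were ZNF8, ZNF714, ZNF362 and ZNF507.

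**Figure D2:**
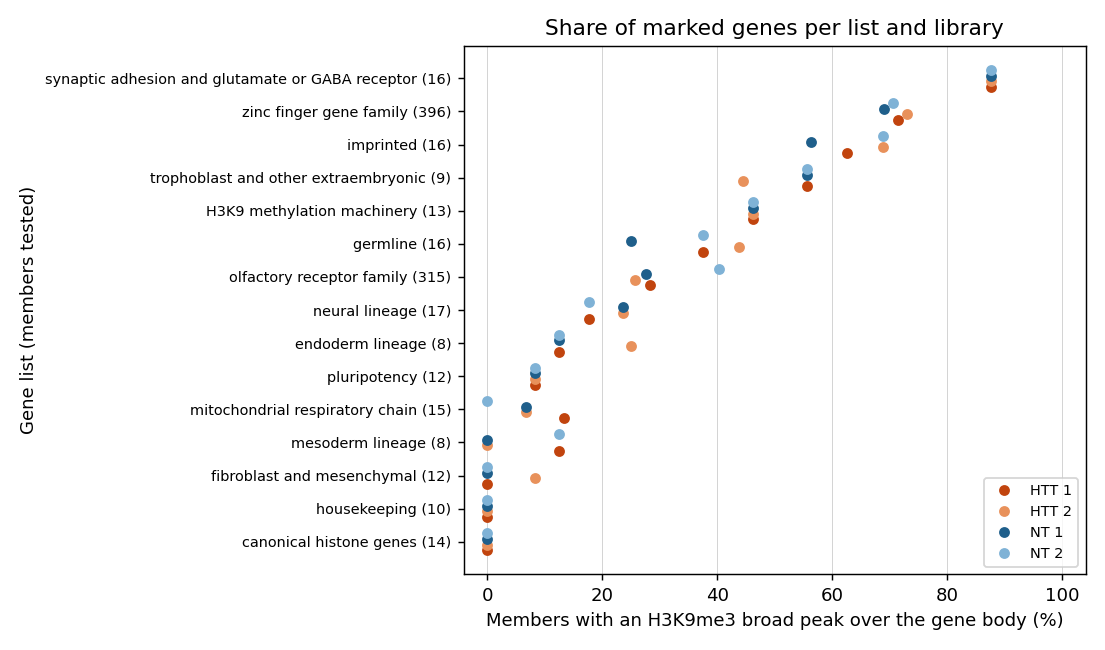
Percentage of the tested members of each gene list (vertical axis, number tested in parentheses) with an H3K9me3 broad peak over the gene body, 1 point per library. Zinc finger genes lie close together in the 4 libraries (273 to 289 of 396), whereas olfactory receptors range from 81 to 127 of 315.

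Olfactory receptor genes, which are expressed mainly in sensory neurons of the nose, were marked at more members in NT shRNA replicate 2 than in the other libraries. A peak lay on 89 and 81 of 315 members in the HTT shRNA libraries, on 87 in NT shRNA replicate 1 and on 127 in NT shRNA replicate 2, at percentile 100 in each library. Peaks covered 16.7% and 10.1% of the summed gene length with HTT shRNA, and 4.60% and 36.3% with NT shRNA. OR2L13 and OR3A2 were marked in all 4 libraries, with 97.3% and 96.9% of their bodies covered in NT shRNA replicate 2. Of 39 NT-only genes 10 were olfactory receptors, at 6 loci (Fisher's exact test, adjusted p = 1.83e-06), against 1 of 219 HTT-only genes (OR10A5, adjusted p = 0.495). The same number, 10, was found among the 111 genes marked only in HTT shRNA replicate 1 and NT shRNA replicate 2, a pair that crosses the groups. With a fold enrichment of at least 4, 1 of 12 NT-only genes was an olfactory receptor (Fisher's exact test, adjusted p = 1).

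Imprinted genes, which are expressed from 1 parental allele, were marked more often than random lists in all 4 libraries. Of 16 members 10 and 11 had a peak with HTT shRNA and 9 and 11 with NT shRNA (percentiles 99.8, 99.9, 99.5 and 99.95), and 9 were marked in all 4. KCNQ1 was covered over 15.1%, 13.6%, 3.14% and 17.0% of its body in HTT shRNA replicates 1 and 2 and NT shRNA replicates 1 and 2. ZIM2 was covered over 53.5%, 32.5%, 10.1% and 100% in that order. Of 9 trophoblast and other extraembryonic genes 5, 4, 5 and 5 were marked in the same order, at percentiles of 99.5, 96.0, 99.8 and 99.5. With random lists matched on chromosome too, the percentile was 84.7 in HTT shRNA replicate 2. The pregnancy-specific glycoprotein genes PSG1 and PSG3 lay wholly inside peaks in NT shRNA replicate 2. PSG1 was covered over 57.5% and 5.25% in the HTT shRNA libraries and over 7.09% in NT shRNA replicate 1, and PSG3 over 34.3%, 34.0% and 5.16% in that order. No member of these lists was HTT-only or NT-only.

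Most pluripotency, neural, mesoderm and endoderm markers had no peak, at numbers within the range of random lists of like gene length. Percentiles ran from 42.0 to 56.5 for pluripotency, 18.98 to 61.3 for neural, 10.4 to 48.7 for mesoderm and 28.0 to 58.8 for endoderm genes. Of 12 pluripotency genes only L1TD1, an RNA-binding protein gene, had a peak, and it had one in all 4 libraries, over 36.1% and 33.1% of its body with HTT shRNA and 12.5% and 18.6% with NT shRNA. Of 17 neural lineage genes 3 or 4 were marked per library, among them MAP2 and NCAM1 in all 4. Of 8 mesoderm genes 1, 0, 0 and 1 were marked in HTT shRNA replicates 1 and 2 and NT shRNA replicates 1 and 2, and of 8 endoderm genes 1, 2, 1 and 1. GATA6, an endoderm transcription factor gene, was HTT-only, with 664 and 564 bp covered. Fibroblast and mesenchymal genes had peaks on 0, 1, 0 and 0 of 12 members, at or under percentile 0.96 in each library. Housekeeping genes (10 members) and canonical histone genes (14 members) had no peak in any library, at percentiles of 15.0 to 22.1 and 3.16 to 11.7.

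Synaptic adhesion and receptor genes were marked at 14 of 16 members in each library, which for genes of such length lay within the range of random lists (percentiles 18.1 to 39.0). LRRTM4 and NRXN3 were the named members marked in all 4. Germline genes had peaks on 6, 7, 4 and 6 of 16 members, with SYCP1 and TDRD12 marked in all 4 libraries. Respiratory chain genes had peaks on 2, 1, 1 and 0 of 15 members, and ATP5F1A, a subunit gene of ATP synthase, was HTT-only. Clustered protocadherins had 0 members and cancer-testis antigens 1 member on these chromosomes, and neither list was tested.

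Genes of the H3K9 methylation machinery had peaks at 6 of 13 members in each library, the 6 being marked in all 4 (percentiles 31.9 to 65.0). ATF7IP, a partner of the H3K9 methyltransferase SETDB1, was covered over 7.64% and 10.3% of its body (chromosome 12, 14365682 to 14502930) in the HTT shRNA libraries, and over 2.94% and 4.15% in the NT shRNA libraries. Its relative ATF7IP2 was covered over 17.7%, 18.3%, 7.96% and 27.1% in the same order of libraries. SETDB1 itself was covered over 3.59% and 4.51% with HTT shRNA and over 0.582% and 0.821% with NT shRNA. The median gene marked in all 4 libraries was covered over 4.32% and 4.88% with HTT shRNA, and over 1.05% and 4.16% with NT shRNA. Lower shares in NT shRNA replicate 1 were thus not particular to the genes named here. HTT (chromosome 4, 3074681 to 3243960) lay outside the part of the genome held by NT shRNA replicate 1. Its body was covered over 3.83% and 5.16% in HTT shRNA replicates 1 and 2 and over 2.11% in NT shRNA replicate 2. These shares were not tested, and the exact permutation test used for group values cannot pass 0.05 with 2 libraries per group.

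More protein-coding genes were marked in both HTT shRNA libraries alone than in both NT shRNA libraries alone. HTT-only genes numbered 219 and NT-only genes 39 of 11577, while 2793 were marked in all 4 libraries. The other splits gave 24 and 87 genes (replicates numbered 1 against those numbered 2) and 111 and 55 genes (HTT 1 with NT 2 against HTT 2 with NT 1). In every split the pair that held NT shRNA replicate 1 had the lower count. With 3 splits no share under 0.05 is possible. HTT-only genes numbered 59 with a fold enrichment of at least 4, and 75 with at least 10% of the gene body covered. NT-only genes numbered 12 and 10 under these settings. Leaving out 1 library gave 347 to 587 HTT-only and 103 to 187 NT-only genes, and without NT shRNA replicate 1 the counts were 347 and 187.

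The HTT-only genes of largest covered length were STPG4, ANKDD1A, DHX57, SEC31B, FDX1, DACT3, NEXN, CCNT1, ZNF362 and PDHX. STPG4 (chromosome 2, 47086991 to 47155308) had 3921 and 3571 bp under peaks in HTT shRNA replicates 1 and 2. DACT3, a regulator of Wnt signalling (chromosome 19, 46647551 to 46661182), had 1870 and 3284 bp, which is 13.7% and 24.1% of its body. CCNT1, the cyclin of the elongation factor P-TEFb, had 1671 and 2221 bp. PDHX, a component of the pyruvate dehydrogenase complex, had 3235 and 1573 bp. The median HTT-only gene had 671 and 825 bp covered, against 4146 and 4591 bp for a gene marked in all 4 libraries. The latter genes were longer (median 90975 against 43790 bp). As shares of the gene body the medians were 1.65% and 1.97% for HTT-only genes, against 4.32% and 4.88%.

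The NT-only genes of largest covered length were AMY2B, PDIA2, OR4K17, TMEM218, LOC124908048, TOM1L1, OR2T8, PRR9, H2BN1 and POTEC. OR4K17 (chromosome 14, 20110739 to 20122199) had 506 and 10570 bp under peaks in NT shRNA replicates 1 and 2, and POTEC had 246 and 29972 bp. AMY2B, a pancreatic amylase gene, had 624 and 1095 bp. TOM1L1 had 661 and 354 bp. OR4K15 and OR5W2, the other named olfactory receptors, were covered over 100% of their bodies in NT shRNA replicate 2 and over 19.6% and 18.8% in NT shRNA replicate 1. With a fold enrichment of at least 4, only CCNT1, DACT3 and OR4K15 of the 28 named HTT-only and NT-only genes still had a peak in a library of their group, and 25 had none.

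**Figure D3:**
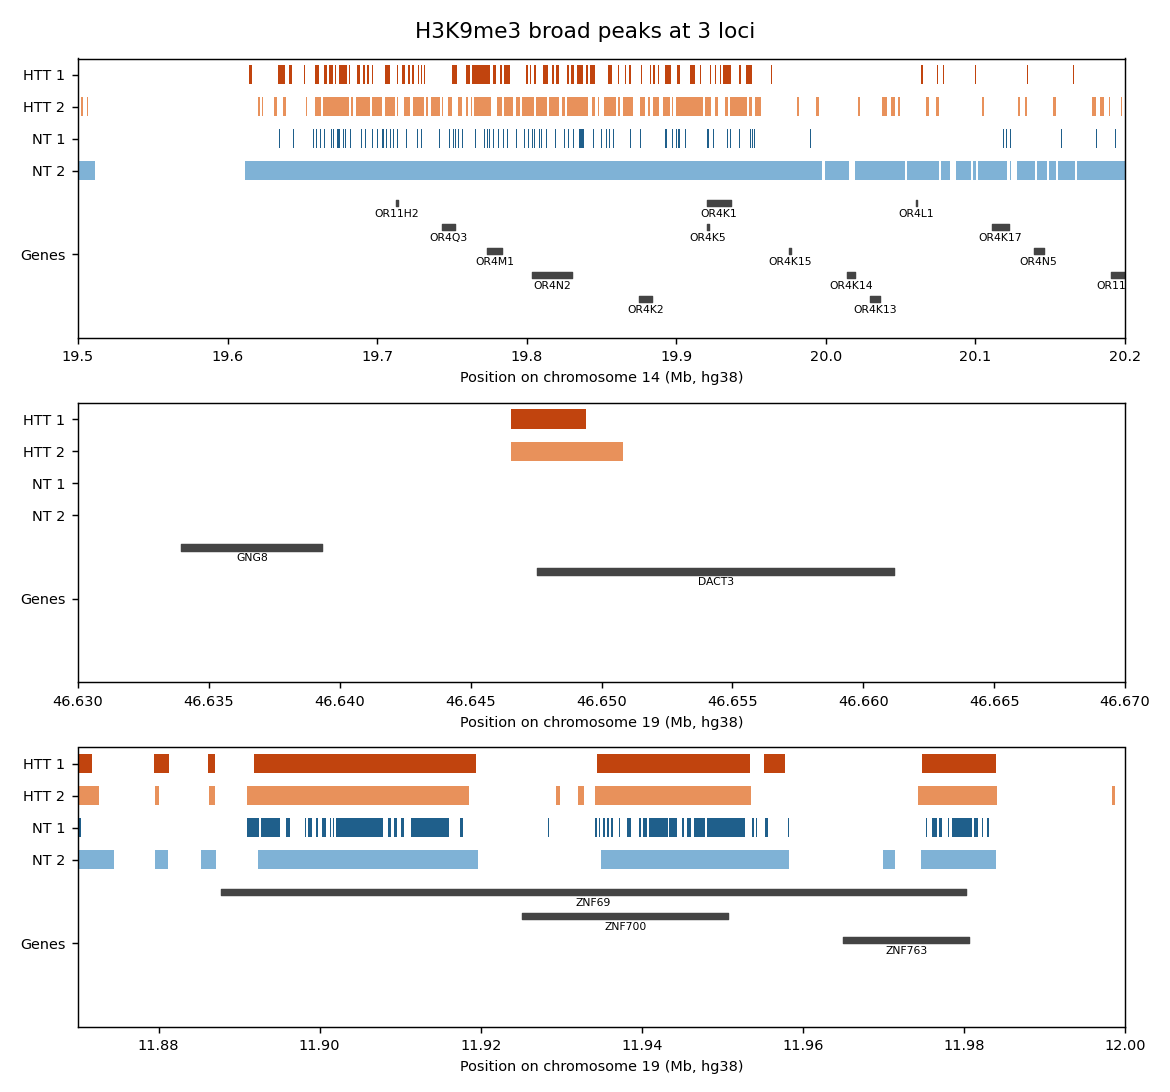
H3K9me3 broad peaks (coloured bars, 1 row per library) and protein-coding genes (grey bars) at 3 loci, against the hg38 position in Mb: an olfactory receptor cluster on chromosome 14, DACT3 on chromosome 19 and the zinc finger gene ZNF69 on chromosome 19. NT 2 has 15 peaks in the olfactory receptor window and HTT 1, HTT 2 and NT 1 have 73, 67 and 234, DACT3 has a peak in both HTT libraries and in neither NT library, and ZNF69 is marked in all 4.

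Merging the 4 lists gave 50010 regions, of which 13186 were marked in all 4 libraries and 20647 in 1 library. HTT-only regions numbered 2284 and NT-only regions 1163. The crossed split gave 2478 and 744 regions, so a split that mixes the groups gave a count as large as the real one, and the split by replicate number gave 343 and 1452. The HTT-only regions of largest covered length were on chromosome 16 (29206026 to 29209505 and 2621580 to 2624713), chromosome 2 (57826072 to 57830354) and chromosome 19 (49320267 to 49324008, in SLC6A16, and 46646528 to 46650834, reaching into DACT3). The NT-only regions of largest covered length, by the smaller value of the pair, were on chromosome 17 (24211552 to 24213244, 24250576 to 24252261 and 25003964 to 25005578) and chromosome 16 (37447887 to 37462078 and 37201804 to 37218963). They held no protein-coding gene and lay in the centromeric parts of these chromosomes. The widest NT-only region spanned 58767 bp. With the narrow lists the counts were 2127 HTT-only and 4182 NT-only regions, and with a fold enrichment of at least 4 they were 153 and 190, so the larger count changed sides. Leaving out 1 library gave 3259 to 8538 HTT-only and 2184 to 16020 NT-only regions, and without NT shRNA replicate 1 the counts were 3259 and 6386.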

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

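The tests on the list settings of NT shRNA replicate 1, on the joining of peaks and the places of joined domains, on the share of wide domains and on the splits of the libraries were chosen after the results had been seen. No group held enough samples for a search for outlying libraries.

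Signal outside the compared chromosomes drew attention in 2 places. NT shRNA replicate 2 was the only list that reached unplaced sequences, and it held 604 peaks on 148 of them, covering 7.92 Mb with a median fold enrichment of 2.68, against 2.38 over all peaks of that list. On chromosomes 3 to 6 and 20 to 22, which the list of NT shRNA replicate 1 did not hold in full, 149 of 4978 protein-coding genes had a peak in both HTT shRNA libraries and not in NT shRNA replicate 2, and 64 had one in NT shRNA replicate 2 and in neither HTT shRNA library.

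The short peaks of NT shRNA replicate 1 may come from another peak calling setting. Its narrowest broad peak was 51 bp, against 289, 282 and 294 bp in HTT shRNA replicates 1 and 2 and NT shRNA replicate 2. In each of the 4 broad lists the smallest gap between peaks, less 1 bp, was exactly 4 times the narrowest peak (205 bp in NT shRNA replicate 1, 1129 to 1177 bp in the others), so both lengths scaled together. Of its covered length 87.2% lay inside peaks of NT shRNA replicate 2, and 83.2% of its peaks touched one of them, while 5565 of its 24305 regions were marked in no other library. In the narrow lists the smallest gap between peaks also differed, at 51 bp in NT shRNA replicate 1 and 76 bp in each of the other libraries. What set the shorter lengths is not given in the sources used here, and a difference in read depth could not be examined.

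NT shRNA replicate 2 held 302 peaks over 50 kb, of which 206 contained no protein-coding gene, and the 3 explanations weighed here remain open. Many of these peaks lay in or beside the centromeric parts of their chromosomes, among them the widest (chromosome 15, 18266429 to 19561035). Peaks there were not examined separately. When peaks within 5 kb were joined, the domains over 50 kb numbered 181, 124 and 185 in HTT shRNA replicates 1 and 2 and NT shRNA replicate 1, against 199 in NT shRNA replicate 2 (smallest count 124). These joined domains covered at least 50% of only 106, 58 and 87 of the 302, and the covered length still differed (93.9, 93.5, 68.0 and 133.1 Mb), so how far fragmentation accounts for the difference stays open. The HTT shRNA libraries covered more of a domain where its fold enrichment in NT shRNA replicate 2 was higher. Spearman's rho was 0.389 across 302 domains, which are not independent replicates (permutation p = 1e-04, the smallest that 10000 permutations give). Weaker enrichment or fewer reads in the HTT shRNA libraries would give a positive rho. A partial loss of a shared mark would give one too, so the rho does not decide between them. A loss of wide domains on HTT knockdown also stays open. Of the covered length of NT shRNA replicate 1, 27.8% lay in these domains, against 24.6% and 23.0% in the HTT shRNA libraries. NT shRNA replicate 1 covered 11.6% of the domains and the HTT shRNA libraries 39.1% and 35.5%. Both measures count the same base pairs, and the second follows list size (17.2 against 65.2 and 63.6 Mb). The first rests on a single NT shRNA library with short peaks, so neither decides.

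The excess of HTT-only (219) over NT-only genes (39), a ratio of 5.62, was weighed against the state of the lists. With the same number of peaks from every list the ratio was 7.52, which decides nothing about longer HTT shRNA lists, because the longest list was NT shRNA replicate 1 (61346 peaks) and shortening it lowers the NT-only count (25). Without NT shRNA replicate 1 the ratio was 1.86. There HTT-only rests on 2 libraries and NT-only on 1, and the ratio without any effect is unknown. In each of the 3 splits the pair that held NT shRNA replicate 1 had fewer genes (39 against 219, 24 against 87, 55 against 111). A lower count thus went with that library whichever library it was paired with. The direction of the excess therefore cannot be credited to the shRNA. Whether the short peaks of that library set the lower counts was not tested. Only 1 of the 3 splits gave as many genes in 1 pair, the highest other count being 111, and 3 splits are too few for a share under 0.05. A gain of H3K9me3 at these genes on HTT knockdown stays open and was not tested apart from these counts.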

How the results depend on the processing

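Alternatives named in the methods as chosen after seeing the data are marked as added here. The planned filter on p, the start site window and the use of all contigs were not run, because p is missing for most peaks, the gene table has no strand, and the lists break off. Depth limits cannot be given without read counts.

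The log2 ratio of covered length turned positive with a replicate block (0.55) and the added crossed block (0.55). The added difference of mean log2 values, with no block, is the same number (0.55), so the averaging of logs turned the sign, not a pairing. It also turned with the added settings of peaks of 300 bp or wider (0.047), no peaks touching a peak over 50 kb (0.21) and 10 kb windows (0.18). It was -1.74 with a fold of at least 4 and -0.62 in the narrow lists, and ranged from -0.82 to 1.91 when 1 library was left out. Values per library are not given for the fold filter and the narrow lists. The ratio of peak number turned positive with joining within 1 kb (0.17) and with the added settings of 300 bp (0.65), joining within 5 kb (0.31) and 19 chromosomes without NT shRNA replicate 1 (0.28), and ranged from -0.68 to 0.30 when 1 library was left out. Joining within 1 kb could alter only the list of NT shRNA replicate 1, because the smallest gap in the other broad lists was 1129 to 1177 bp. The difference in overlap kept its sign except without HTT shRNA replicate 1 (-13.4) or HTT shRNA replicate 2 (-15.7), and reached 25.6 without NT shRNA replicate 2. With 1 library left out only 1 within-group pair remains, and the sign followed which pair that was.

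Counts of HTT-only and NT-only regions were 153 and 190 with a fold of at least 4, 3464 and 183 with at least 50% of the region covered, and 5002 and 435 in 1 kb bins. NT-only regions were 4182 in the narrow lists. Among added settings, HTT-only regions were 1478 at or above the median fold, NT-only regions were 268 with peaks of 300 bp and 472 with joining within 5 kb, and leaving out NT shRNA replicate 1 together with the extension to 19 chromosomes gave 5359 and 9858. Leaving out 1 library gave 3259 to 8538 and 2184 to 16020. HTT-only and NT-only genes were 59 and 12 with a fold of at least 4 and 75 and 10 with at least 10% of the body covered. NT-only genes were 25 with equal list lengths and, under added settings, 5 with peaks of 300 bp and 67 at or above the median fold. Leaving out 1 library gave 347 to 587 and 103 to 187 genes. Without NT shRNA replicate 1, counts were 347 and 187 (496 and 251 on 19 chromosomes, added). The cause of these shifts was not tested. HTT-only outnumbered NT-only genes in every setting. Each used the short-peaked list of NT shRNA replicate 1 or set 2 libraries against 1, so none tests the direction.

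The number of lists past the adjusted threshold was 1 (olfactory receptors among NT-only genes) and fell to 0 with a fold of at least 4 and, under added settings, with peaks of 300 bp and at or above the median fold. The adjusted p of that list was 1, 1 and 0.0665 there and between 6.92e-09 and 0.0132 in the 6 others. Lists above percentile 95 in all 4 libraries numbered 4, and 3 with random lists matched on chromosome too, the trophoblast and other extraembryonic list falling to percentile 84.7 in HTT shRNA replicate 2. Of the named HTT-only and NT-only genes, 25 of 28 had no peak left with a fold of at least 4, 9 of 28 showed no difference at or above the median fold (added), 2 of 25 (NEXN and OR10A5) showed none in the narrow lists, and OR4K15 showed none without peaks that touch a peak over 50 kb (added).

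The labels do not say that a replicate number marks a shared day, so the libraries share only a number. The correlation of the replicate differences of the groups over 100 kb windows was -0.132. The block left the counts at 2284 and 1163 regions and 219 and 39 genes, as its construction requires, and so did the crossed block.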

Other observations

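The groups below belong to the fixed gene lists. Reporting them from the 3 broad lists that hold chromosomes 3 to 6 and 20 to 22 in full, and the choice of the members named, came after the data had been seen. Clustered protocadherins, cell adhesion genes of chromosome 5 that neurons use for self-recognition, had an H3K9me3 peak at most members. A peak lay on 45 and 49 of 53 members in HTT shRNA replicates 1 and 2 and on 42 in NT shRNA replicate 2, and peaks covered 13.6%, 16.7% and 12.5% of the summed gene length. PCDHGA1 was covered over 29.8%, 30.5% and 28.3% of its body, and PCDHB15 over 92.6%, 84.1% and 67.8%. PCDHB4 was covered over 27.6% and 62.7% with HTT shRNA and had no peak in NT shRNA replicate 2, and PCDHB16 over 50.9% and 38.5% with none. Protocadherin genes of the alpha and gamma groups share their last exons, so neighbouring members are not independent.

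The core pluripotency genes POU5F1 and SOX2, and SALL4 and DNMT3B, had no peak in any of the 3 lists. LIN28B was covered over 3.71%, 8.14% and 1.25% in HTT shRNA replicates 1 and 2 and NT shRNA replicate 2. TASOR, a subunit of the HUSH silencing complex, had 1023 and 568 bp covered with HTT shRNA and 0 bp in NT shRNA replicate 2, and MORC2, a HUSH partner, had 1398, 1953 and 653 bp. SDHA was the only housekeeping gene with a peak (17.8%, 15.6% and 17.6%), and PDGFRA was covered over 23.3%, 19.5% and 21.6%.

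HTT-only and NT-only regions differed in where they lay. Of HTT-only regions 43.9% touched a protein-coding gene, as did 16.2% of NT-only regions and 38.6% of regions marked in all 4 libraries. These are counts in 4 libraries with no test between groups, and no such shares were computed for the other splits.

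Windows of 1 Mb ranked much alike in all libraries by covered length. Spearman's rho across 1462 windows, which are not independent replicates, was 0.896 between the HTT shRNA libraries and 0.778 between the NT shRNA libraries. With NT shRNA replicate 2 it was 0.891 for HTT shRNA replicate 1 and 0.805 for HTT shRNA replicate 2. In 10 kb windows the ranks were less alike, with rho from 0.512 to 0.607 over all pairs of libraries.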
